A study of Mus musculus with 2 samples.

How the data were processed

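Histone H3 trimethylated at lysine 27 (H3K27me3), the mark laid down by Polycomb repressive complex 2, was profiled by chromatin immunoprecipitation and sequencing in stomach from mouse embryos of strain B6NCrl at embryonic day 15.5. The labels give 1 group of 2 biological replicates. Replicate 1 pooled tissue from 78 embryos and was sequenced as 2 technical replicates, and replicate 2 pooled tissue from 62 embryos and was sequenced as 3. Both pools held male and female embryos in a ratio the labels do not give. The labels name sequencing instruments for replicate 2 only, so a difference between sequencing runs cannot be separated from the replicate.

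Peak lists of replicate 1, replicate 2 and the pooled reads and a list of replicated peaks, in narrowPeak format on the mm10 build, were the starting point. The deposited readme texts state that each replicate list was made from the filtered alignments of that replicate together with 2 further files, that the pooled list used the alignments of both replicates, and that the replicated list was derived from the other 3 lists. The rule behind the replicated list, the aligner, the peak caller, its version and its threshold are not given in the sources used here. The fold value of a peak is a linear ratio, as deposited by the authors in the signal column, and was read here as enrichment over control from the file type and the range of its values. The strength of a peak was given by the authors as −log10 of the p-value and −log10 of the q-value. The lowest −log10 p was 2.00 in the list of replicate 1 and 2.03 in the other lists. These scores belong to single peaks and were used only to describe, rank or filter peaks within a list and to correlate overlapping peaks. Peak lists carry no read counts, so the sequencing depth of each replicate is unknown and no interval that needs it is given. Intervals on shares of peaks or genes are 95% Wilson intervals and cover counting of peaks or genes only, which are not independent units.

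Peaks on chromosomes 1 to 19 and X were kept, which left out 1 peak of replicate 2 and 1 of the pooled list on an unplaced sequence. No peak ran past the end of a chromosome of the GRCm38.p6 reference, the assembly that mm10 names. Genes came from the GENCODE M21 annotation, which holds 21755 protein-coding genes on these chromosomes. A gene was called marked when at least 1 bp of a replicated peak lay within 1 kb of the 5′ end of its gene record. The share of the 5 kb window centred on the 5′ end that lay in peaks was computed in each replicate and is given as mean ± SD (n = 2). The gene record starts at the most upstream transcript, so for Hoxa3, Hoxb3, Hoxc5, Hoxd3 and Hoxd4 the window lies near or among the neighbouring, more posterior genes. Other starts of a gene did not enter the main call, so an unmarked gene may have a peak at another start. When any annotated transcript start counted, 3308 genes were marked, against 2869. Promoters with an observed/expected CpG ratio of at least 0.6 and a GC content of at least 50% within 500 bp on either side were called CpG-rich. Domains were made by joining replicated peaks within 3 kb. Peak midpoints were assigned to promoter (within 1 kb of any transcript start), exon, intron or intergenic sequence, in that order.

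Chance levels came from 100 seeded shuffles of the peaks within each chromosome, outside runs of unknown bases. The smallest permutation p that 100 shuffles can give is 0.0099 one-sided and 0.0198 two-sided. Marking of 31 gene lists was tested with the two-sided Fisher exact test against all other protein-coding genes, with Benjamini-Hochberg adjustment over the lists and a threshold of 0.05. Lists share members, and neighbouring genes of a cluster are not independent. Genes marked in 1 replicate only were compared with the two-sided exact McNemar test, which compares these libraries only. The lists, tests and main alternatives were fixed before the data were examined. The McNemar test was fixed for all genes together, and its use within X, the autosomes and single lists was added. The named genes were taken by a rule fixed at the same time: genes in the 10 longest domains, the 3 marked members of highest coverage and the first 3 unmarked members of each list in alphabetical order, the 5 replicated peaks of highest fold, and up to 3 members of each list marked in 1 replicate only. Values are printed for part of these genes. List symbols were matched to the annotation directly or through RefSeq synonyms. All were found except 4 of the 24 imprinted genes, H19, Kcnq1ot1, Meg3 and Airn, which are not annotated as protein coding.

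Alternatives covered the overlap that counts as shared, stricter p and q thresholds, equal numbers of top peaks, the window around the 5′ end, any transcript start, the pooled list, each replicate alone, the CpG definition, random lists matched on CpG, covered bases in place of midpoints and the joining distance. Leaving out chromosome X was added after the data were seen.

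The computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pysam 0.24.0, matplotlib 3.10.9, samtools 1.23.1 and bedtools 2.31.1. They were tested on simulated data. With 40.0% of the peaks of replicate 1 planted in a random list, 41.2% were found to overlap, and 1.68% overlapped with none planted. All 200 genes given a planted peak were called marked. Of 620 random gene lists tested with shuffled peaks, 1 was called. Shuffled peaks mark 2.38% of genes, against 13.2% for the replicated list, and the random lists held scattered genes. This count therefore says little about false calls among the real lists. When 60% of members were marked over a background of 13%, 43 of 50 lists of 16 genes, 49 of 50 lists of 20 genes and 50 of 50 lists of 48 genes were called.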

Results

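H3K27me3, a histone mark associated with gene repression by Polycomb complexes, was mapped in the stomach of mouse embryos at day 15.5 in 2 biological replicates. The design has 1 tissue and 1 stage, so the comparisons it implies are between the replicates, and between genes that carry the mark and genes that do not. The authors called 51563 peaks in replicate 1, 48228 in replicate 2 and 61496 in the pooled reads on chromosomes 1 to 19 and X. The replicated list held 19816 peaks with a median width of 519 bp, which covered 17.4 Mb, and each was identical to a peak of the pooled list. The name of this list is the authors', and 84.6% of its peaks touched a peak of both replicates. The read depth behind the lists is unknown.

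The 10 longest H3K27me3 domains lay over all or part of each of the 4 Hox clusters and over genes of other developmental transcription factors. The longest spanned 139 kb on chromosome 15 (102895512 to 103034538, mm10) over Hoxc13 to Hoxc4, and peaks covered 78.7 ± 2.74% of it (SD, n = 2). The next spanned 127 kb on chromosome 2 (74642786 to 74769735) from Evx2 through the Hoxd genes, with 82.8 ± 4.23% covered. The domain of Hoxa5 to Hoxa13 on chromosome 6 (52196167 to 52281686), which also held the upstream 5′ end of Hoxa3, was 85.5 kb long and that of Hoxb9 to Hoxb4 on chromosome 11 (96245960 to 96318462) was 72.5 kb long. Domains of 89.8 kb over Pax3, a neural crest and muscle progenitor factor, over Zic4 and Zic1 (chromosome 9, 91347572 to 91422521), of 62.9 kb at Tbx5, of 54.2 kb at Dmbx1 and of 53.8 kb at Pax7 were also among the 10. The remaining domain, 76.1 kb on chromosome 7 (79493765 to 79569903), held no 5′ end of a protein-coding gene. It contained the long noncoding RNA Mir9-3hg, host of the microRNA Mir9-3, and the long noncoding RNA Gm35040. Joining replicated peaks within 3 kb gave 7432 domains, of which 500 were at least 10 kb long and 176 at least 20 kb. The number of at least 10 kb was 331 with a joining distance of 1 kb and 917 with 10 kb, and it was 807 from the peaks of replicate 1 alone.

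Of the 5 replicated peaks of highest fold, the first, with an authors' fold of 8.82, lay on chromosome 11 (118567120 to 118573517) at a transcript start within Rbfox3, a neuronal splicing factor gene. The others were within Shank1, which encodes a postsynaptic scaffold protein (fold 8.16), over the transcription factor gene Egr4, over Olig1, a factor of the oligodendrocyte lineage (7.95), and over Onecut3 (7.92).

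Peaks lay at promoters far more often than chance placement gave. Of the replicated peaks, 27.9% (95% interval 27.3 to 28.5%) had their midpoint within 1 kb of a transcript start, against 6.43% of shuffled peaks, a 4.34-fold difference. Exons outside promoters held 7.95% of peaks against 3.39% by chance. Introns held 0.774 times and intergenic sequence 0.661 times the share of shuffled peaks. Each of these shares lay outside the range of 100 shuffles (permutation p = 0.0198, two-sided, the smallest possible).

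Of 21755 protein-coding genes, 2869 (13.2%, 95% interval 12.7 to 13.6%) were marked, against 2.38% with shuffled peaks. Called in each replicate separately, 3605 genes were marked in replicate 1 and 3557 in replicate 2, with 2897 marked in both. Of the 2869 genes, 2709 were marked in both replicates called separately, 74 in replicate 1 only, 84 in replicate 2 only and 2 in neither. Hoxb4, Myocd and Cbx4 were among those of replicate 1 only, and Wnt8b, Bmp7 and Olfr222 among those of replicate 2 only. Some genes marked in both replicates were unmarked in the replicated list, among them Hoxb2, Cbx2 and Ednrb. CpG-rich promoters were marked in 16.5% of 9741 genes and other promoters in 10.5% of 12014 (log2 odds ratio 0.76, two-sided Fisher exact p = 3.1e-39). The relation was not monotonic. With genes ranked by observed/expected CpG, 0.873% were marked in the lowest decile, 26.6% in decile 5, 25.9% in decile 6 and 10.3% in the highest decile. With a stricter definition of CpG-rich the log2 odds ratio was 0.14 (two-sided Fisher exact p = 0.039).

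**Figure D1:**
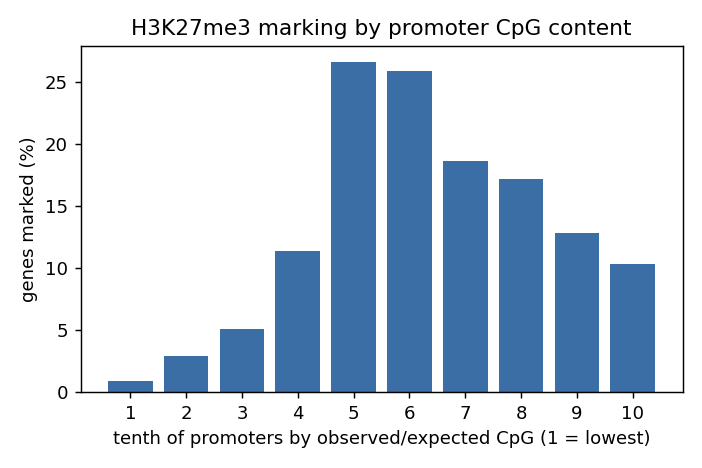
Percent of protein-coding genes marked by H3K27me3 (y axis) in each decile of genes ranked by the observed/expected CpG ratio of the promoter (x axis, 1 is lowest). Marking is highest in deciles 5 and 6, at 26.6% and 25.9%, and is 10.3% in the highest decile.

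Regulators of the central nervous system and of the limb and genes for secreted signals were marked in most or all cases. All 48 listed regulators of the central nervous system were marked (adjusted Fisher p = 6.4e-42), with 85.4 ± 2.81% of the 5 kb window in peaks (SD, n = 2). Coverage reached 100 ± 0% at Tlx3, 99.4 ± 0.919% at Six3 and 98.3 ± 2.47% at Pax7. All 19 Wnt ligand genes were marked (adjusted Fisher p = 1.1e-16), as were 19 of 20 regulators of limb and genital development, where Fgf10 was the exception (adjusted Fisher p = 1.6e-15). Fgf10 was judged at the most upstream start of its gene record only. Of 32 BMP, hedgehog and FGF signals and their antagonists, 27 were marked (adjusted Fisher p = 1.3e-18), among them Gdf7 with 100 ± 0% coverage, Fgf3 with 96.3 ± 5.26% and Ihh with 94.8 ± 5.25%. In total 19 of the 31 lists were marked more often than other genes and 4 less often.

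Among the lists of other gut tube organs, those of pancreas and of lung and thyroid were marked more often than other genes. Of 20 pancreas genes 16 were marked (adjusted Fisher p = 8.0e-11), led by Neurog3, the factor of endocrine progenitors (97.1 ± 2.14% coverage), Pax6 (97.0 ± 2.36%) and Neurod1 (92.8 ± 0.551%). Pax6, Neurod1, Nkx2-2 and Nkx6-1 are counted in the list of central nervous system regulators as well. The hormone genes Gcg and Ins1 and the digestive enzyme gene Cpa1 were unmarked, with 0% coverage. Of 14 lung and thyroid genes 8 were marked (adjusted Fisher p = 2.4e-04), led by Foxe1 and Nkx2-1, each with 97.1% coverage. Of 20 liver genes 4 were marked, Hhex, Prox1, Tbx3 and Cebpa, of which Cebpa was chosen after its values were seen, and the list did not pass the test (adjusted Fisher p = 0.347). Among the intestinal genes 6 of 20 were marked, including the intestinal identity factor Cdx2 with 88.5 ± 7.15% coverage. The enterocyte genes Alpi and Apoa4 were unmarked. The marked members also included the posterior Hox genes Hoxb13 (97.1 ± 0.410%) and Hoxd13 (83.0 ± 2.97%), which are counted in a Hox list as well. The intestinal list was not tested without these Hox genes. The intestinal list missed the threshold (adjusted Fisher p = 0.051) but passed it with a 500 bp window (adjusted Fisher p = 0.028), with peaks of −log10 p of at least 5 or −log10 q of at least 2 (adjusted Fisher p = 0.038 and 0.041) and with the peaks of replicate 2 alone (adjusted Fisher p = 0.014). Over all alternatives its adjusted Fisher p ran from 0.014 to 0.156, and it passed against random lists matched on CpG (adjusted permutation p = 0.041).

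Many genes that regulate the stomach itself carried the mark in this whole tissue. Peak lists of a whole tissue cannot show which of its cells carried the mark. Of 20 endoderm regulators 13 were marked (adjusted Fisher p = 2.7e-07), with the highest coverage at Pdx1, a factor of the posterior stomach, duodenum and pancreas (87.5 ± 6.19%), Sox21 (71.0 ± 2.66%) and Sox2, a factor of the anterior gut (68.6 ± 7.92%). Ehf, Elf3 and Hnf4a were unmarked, with 0% coverage. Of 22 mesenchyme regulators 15 were marked (adjusted Fisher p = 1.2e-08), with the highest coverage at Foxf1 (96.3 ± 0.353%), Hand1 (92.4 ± 4.40%) and Six2 (91.5 ± 1.36%). Barx1, a regulator of stomach mesenchyme chosen after its values were seen, had 80.0 ± 5.47% coverage. Meis1 and Meis2 had none. Of 20 genes of the enteric nervous system 12 were marked (adjusted Fisher p = 2.5e-06), led by Tubb3, Foxd3 and Ascl1.

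Genes for differentiated products of the stomach were mostly unmarked. Of 20 gastric genes 2 were marked, Sst, which encodes somatostatin (41.8 ± 0.396% coverage), and Cckbr, the gastrin receptor gene (38.6 ± 0.976%), a share that did not differ detectably from other genes (adjusted Fisher p = 1). The parietal cell proton pump gene Atp4b had 0% coverage, and its partner Atp4a was marked in replicate 2 only. Of 16 smooth muscle genes 4 were marked, Cnn1, Des, Synm and Myocd (adjusted Fisher p = 0.173), with 41.0 ± 4.50% coverage at Cnn1 and none at Acta2 or Actg2. From the peaks of replicate 1 alone this list passed, with an adjusted Fisher p of 0.048, the lowest of a range up to 0.445. Squamous epithelium genes were marked in 4 of 16 cases, Pax9, Lor, Sfn and Perp (adjusted Fisher p = 0.173), and blood and immune genes in 5 of 24, Pax5, Tal1, Ikzf1, Ebf1 and Gfi1b (adjusted Fisher p = 0.261). Of these, Perp, Ebf1 and Gfi1b were chosen after their values were seen.

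Germline and pluripotency genes were marked in 12 of 18 cases (adjusted Fisher p = 5.1e-07), led by T, the mesoderm factor Brachyury, at 94.1 ± 1.61% coverage. The germline genes Dazl and Ddx4 were unmarked, with 0% coverage, and Dppa3 was unmarked as well. Skeletal muscle and cardiac muscle genes were each marked in 8 of 16 cases (adjusted Fisher p = 6.7e-04 for each). Myod1 had 84.5 ± 1.85% coverage, while the skeletal muscle regulators Myf5 and Myf6 and the cardiac contractile genes Myh6 and Myh7 had 0%. Endothelial genes were marked in 7 of 16 cases (adjusted Fisher p = 0.0039), led by Sox18. The Fox family was marked in 26 of 44 cases and the Sox family in 11 of 19 (adjusted Fisher p = 4.3e-12 and 1.1e-05). Among the imprinted genes 7 of 20 were marked (adjusted Fisher p = 0.016), led by Ascl2, a count that did not pass against random lists matched on CpG (adjusted permutation p = 0.052). Cell cycle inhibitors were marked in 3 of 10 cases (adjusted Fisher p = 0.167), which were Trp73, Cdkn2a and Cdkn2b. Of 20 genes for Polycomb proteins 2 were marked, Cbx8 and Cbx4 (adjusted Fisher p = 1).

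Marking was rarest at genes used in every cell and at chemosensory receptors. None of 30 housekeeping genes was marked (adjusted Fisher p = 0.036), 1 of 80 ribosomal protein genes was, Rpl3 (adjusted Fisher p = 5.9e-04), and 0 of 327 vomeronasal and 2 of 1135 olfactory receptor genes were (adjusted Fisher p = 9.5e-20 and 1.4e-66). The olfactory genes were Olfr222 and Olfr1414. The housekeeping call was lost with a 500 bp window, with peaks of −log10 p of at least 5 and, with Pgk1 marked, from the peaks of replicate 2 alone, over a range of adjusted Fisher p from 0.0092 to 0.064.

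**Figure D2:**
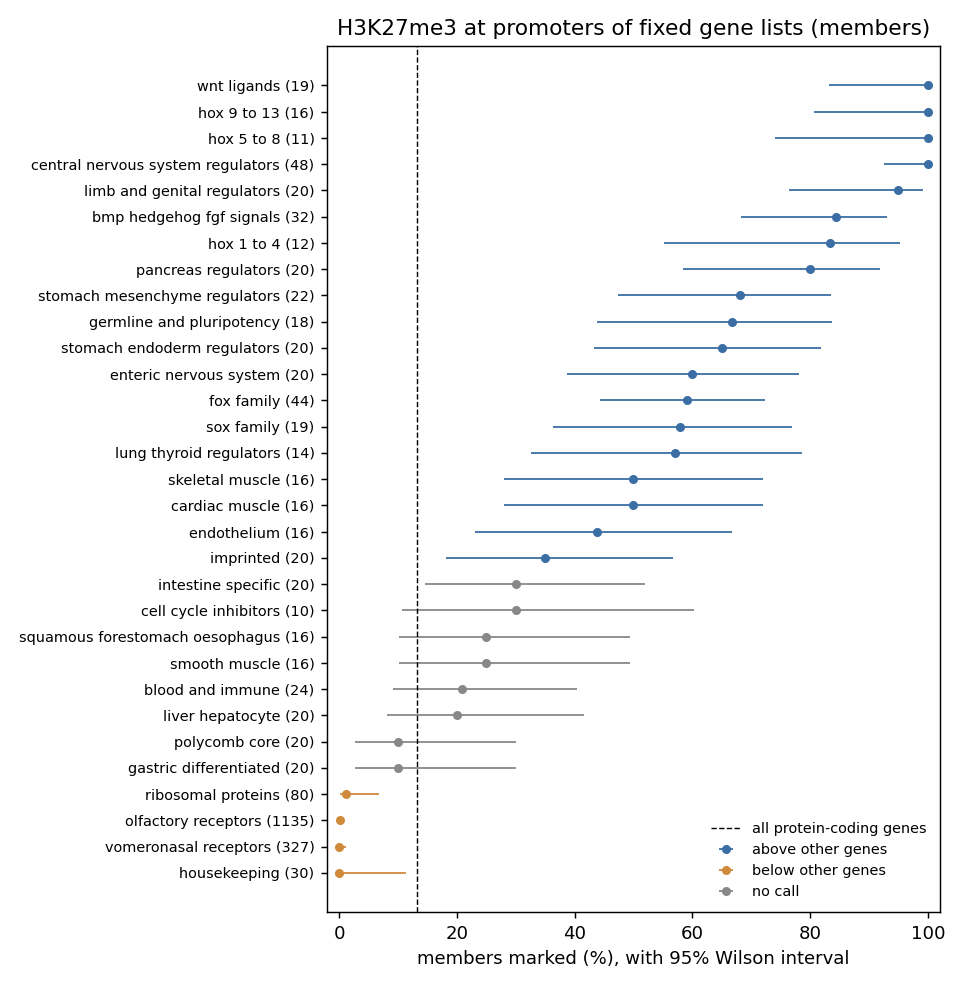
Percent of members marked (x axis) for each of the 31 gene lists (y axis, number of members in brackets). Points are the percent marked and lines the 95% Wilson interval, colours give the outcome of the adjusted Fisher test, and the dashed line is the 13.2% of all protein-coding genes. The list of central nervous system regulators stands at 100% and that of housekeeping genes at 0%.

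Within the Hox clusters, mean coverage was highest at the genes of paralogue groups 9 to 13, which are expressed toward the posterior of the body. All 16 of these genes, all 11 of groups 5 to 8 and 10 of 12 of groups 1 to 4 were marked (adjusted Fisher p = 3.6e-14, 6.4e-10 and 2.1e-07). The 2 unmarked genes were Hoxa2 and Hoxb2, and Hoxb2 was marked in each replicate when called alone. A difference in the number of marked genes between groups 9 to 13 and 1 to 4 was not detected (two-sided Fisher exact p = 0.175). Peaks covered 92.1 ± 1.06% of the 5 kb window in groups 9 to 13, 72.2 ± 4.44% in groups 5 to 8 and 44.7 ± 2.29% in groups 1 to 4 (SD, n = 2), and these means differed by more than their spread between replicates. Single genes varied more, from 4.34% at Hoxa2 to 89.8% at Hoxd3 in groups 1 to 4 and from 81.4% at Hoxd10 to 98.5% at Hoxd12 in groups 9 to 13, and no test across genes was made. Groups 1 to 4 ranged from 22.8 ± 1.92% in Hoxb to 89.3 ± 2.46% in Hoxd, where groups 9 to 13 had 90.8 ± 3.07%. The Hoxd value rests in part on Hoxd3 and Hoxd4, and the Hoxa value on Hoxa3 (81.9%), whose gene records begin upstream among the more posterior genes. Hoxd1, the other Hoxd gene of groups 1 to 4, is not such a record and had 88.2 ± 2.67% coverage. The high Hoxd value thus did not depend on Hoxd3 and Hoxd4. The other Hoxa genes of groups 1 to 4 had at most 24.0% coverage, at Hoxa1.

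**Figure D3:**
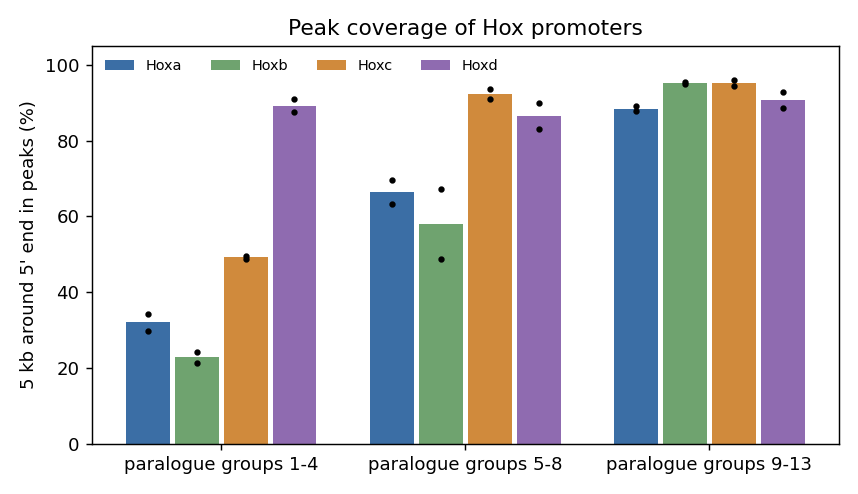
Percent of the 5 kb window around Hox 5′ ends that lies in peaks (y axis), by cluster and paralogue groups (x axis). Bars are the mean of 2 replicates and black points the replicates. Coverage in Hoxa is 32.1% in groups 1 to 4, with Hoxa3 at 81.9%, and 88.4% in groups 9 to 13, while Hoxd is near 90% in both, at 89.3% and 90.8%.

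The replicates shared most of their strong peaks and few of their weak ones. A peak of the other replicate overlapped 39.2% of replicate 1 peaks (95% interval 38.7 to 39.6%) and 43.6% of replicate 2 peaks (43.2 to 44.1%), against 1.74% and 1.86% of shuffled peaks (permutation p = 0.0099, one-sided, the smallest possible). With each list ranked by p and split into 5 equal parts, 83.2% and 87.8% overlapped in the part of smallest p, and 17.4% and 20.9% in the part of largest p. Median width was 644 and 645 bp in the part of smallest p and 229 and 225 bp in that of largest p. Wider peaks meet a peak of the other list more easily, so strength and width were not separated. Requiring 50% reciprocal overlap lowered the shares of all peaks to 20.0% and 21.4%. The authors' fold at the 20193 overlapping pairs correlated across peaks with Spearman's rho of 0.50 and, on the log2 scale, Pearson's r of 0.57. Peaks are not independent replicates, so no p is given.

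**Figure D4:**
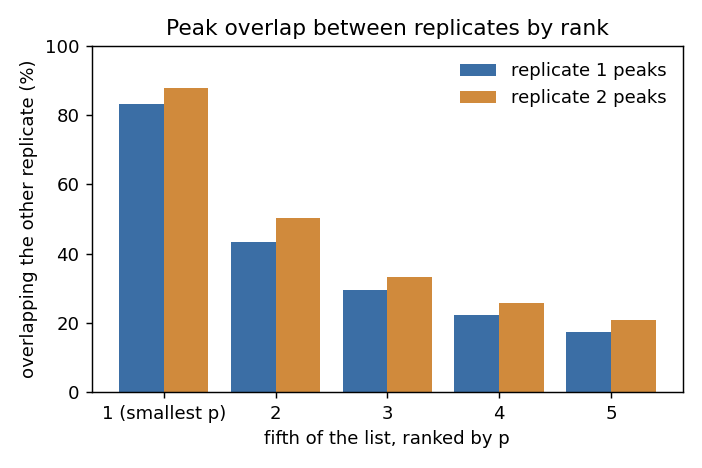
Percent of peaks that overlap a peak of the other replicate (y axis) in 5 equal parts of a replicate's list ranked by the authors' p (x axis, 1 has the smallest p). Bars are the 2 replicates. The share falls from 83.2% to 17.4% in replicate 1 and from 87.8% to 20.9% in replicate 2.

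At the level of genes, 708 were marked in replicate 1 only and 660 in replicate 2 only (two-sided exact McNemar p = 0.204). In 30 of the 31 gene lists at most 3 genes were marked in 1 replicate only, so the exact McNemar test could not give a p below 0.25 there. Of the olfactory receptor genes, 5 were marked in replicate 1 only and 15 in replicate 2 only (two-sided exact McNemar p = 0.041, and 1 after adjustment over the lists). Chromosome X was different. There, 87 genes were marked in replicate 1 only and 26 in replicate 2 only (two-sided exact McNemar p = 7.1e-09). On the autosomes the numbers were 621 and 634 (two-sided exact McNemar p = 0.735). This split by chromosome was not among the tests fixed beforehand, and replicate 1 also had more peaks on X. Genes of a chromosome are not independent, so these p-values describe the 2 libraries only.

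Replicate 1 had 6272 peaks on X and replicate 2 had 1935, a ratio of 3.24, while the ratio on the 19 autosomes lay between 0.930 and 1.08. Peaks covered 1.10% of X in replicate 1, rank 4 of the 20 chromosomes, and 0.324% in replicate 2, the lowest. The replicated list covered 0.294% of X, which ranked 19th, and the pooled list 0.935%. One chromosome out of 20 allows no two-sided exact rank p below 0.1. Of replicate 1 peaks, 12.5% on X and 42.8% on the autosomes overlapped a replicate 2 peak, and of the fewer replicate 2 peaks, 41.6% on X and 43.7% on the autosomes overlapped a replicate 1 peak. The sex ratio of the embryo pools is not in the labels, and the replicates were sequenced as separate sets of technical replicates.

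**Figure D5:**
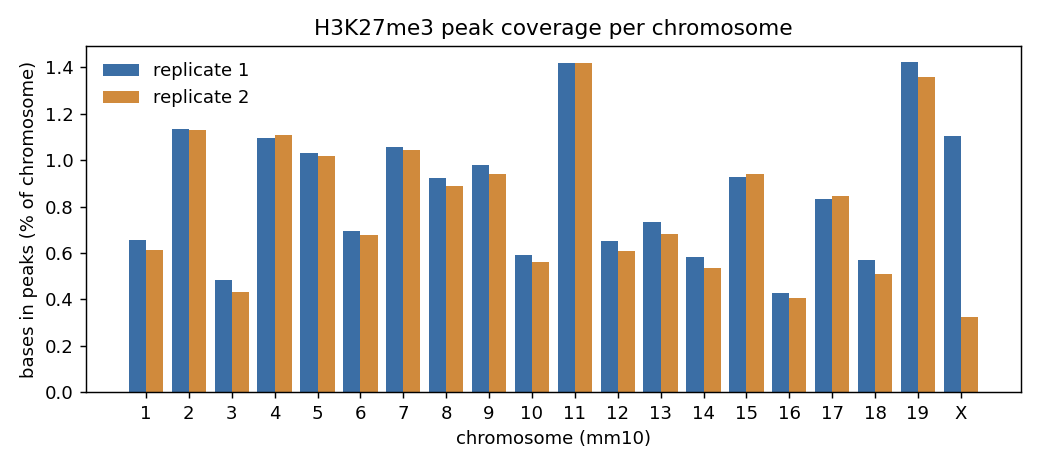
Bases in peaks as a percent of chromosome length (y axis) for each chromosome (x axis). Bars are the 2 replicates. The bars of X stand at 1.10% in replicate 1 and 0.324% in replicate 2, while the autosomal ratios of covered length lie between 0.986 and 1.12.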

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

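Leaving out chromosome X was chosen after the data were seen, and all other alternatives were planned. Of 343 recomputed values 293 kept their direction and side of the threshold or, without a test, moved little (counts by at most 1.5 times, overlap shares within their 95% interval). Numbers of marked genes, enrichment of promoters and exons, depletion of introns and intergenic sequence, the higher marking of CpG-rich promoters, the Hox comparison, which did not pass its test, and the numbers of lists above (19 to 20) and below (3 to 4) other genes held under each alternative run. The read depth is unknown, so its effect was not tested.

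The share of replicate 1 peaks that overlapped replicate 2 was 36.3% when 25% of the peak had to be shared, 27.8% at 50% and 20.0% at 50% reciprocal. It was 52.8% among peaks with −log10 p of at least 5, 49.4% with −log10 q of at least 2, 40.6% for equal numbers of top peaks and 42.8% without chromosome X. For replicate 2 the shares under the first 6 of these were 40.8%, 33.4%, 21.4%, 56.5%, 51.9% and 42.6%. A larger required overlap can only lower them. Spearman's rho was 0.48 at −log10 p of at least 5 and 0.62 at 50% reciprocal overlap. At −log10 p of at least 5 there were 18190, 18111 and 23553 peaks in replicate 1, replicate 2 and the pooled list, and at −log10 q of at least 2 there were 22630, 23039 and 29519, as a stricter threshold keeps fewer peaks.

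The excess of genes marked in replicate 1 only over those in replicate 2 only, 48, was -47 at −log10 q of at least 2, -32 for equal numbers of top peaks and -13 without chromosome X, with no exact McNemar p under 0.05. Domains of at least 10 kb numbered 331 and 917 at joining distances of 1 kb and 10 kb, and from 716 to 807 in single replicates, where domains of any length numbered from 22233 to 23453, since single replicate lists hold more peaks. Coverage of X was 0.324% without replicate 1, 1.10% without replicate 2 and 0.935% in the pooled list.

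Among 217 values of single lists, 3 lost their call, 5 gained one and 5 changed sign without a call. The log2 odds ratio of the gastric list, -0.17, was 0.073 with a 500 bp window and ran from -0.56 to 0.48 in single replicates. That of the Polycomb list, -0.17, was 0.16 with a 2.5 kb window, 0.29 in the pooled list and ran from -0.53 to 0.0097 in single replicates. Neither list passed the threshold in any of these, and the cause was not tested.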

Other observations

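The tests for the X chromosome, the CpG split of 6 gene lists and the gene families and noncoding genes described next were chosen after the results were seen. The test of genes with a single start region was set before its result was seen.

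Families of genes with a shared symbol stem and at least 10 members gave 26 families marked more often and 7 less often than other genes, of 267 tested (Fisher exact test, Benjamini-Hochberg adjusted). All 14 Nkx homeobox genes were marked (adjusted Fisher p = 6.3e-11), and some of them, such as Nkx2-1 and Nkx3-2, are also in the fixed lists. The mark was also found at 13 of 17 Syt genes, which encode synaptotagmins of vesicle release (adjusted Fisher p = 3.4e-07), and at 10 of 14 Htr genes, which encode serotonin receptors (adjusted Fisher p = 3.6e-05). Kcnk potassium channel genes and Chst carbohydrate sulfotransferase genes were each marked in 9 of 14 cases, and Col collagen genes in 19 of 45. On the other side stood the Zfp zinc finger genes with 15 of 394 marked (adjusted Fisher p = 3.4e-08), the Hist histone genes with 0 of 67 and the Mrpl mitochondrial ribosome genes with 0 of 49. Many Zfp and Hist genes are neighbours, so their members are not independent.

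The 5′ ends of 5.60% of 5305 lincRNA genes and 10.3% of 2958 antisense genes were marked, against 13.2% of protein-coding genes. The shares were 3.61% and 3.95% among those over 10 kb from a coding 5′ end. No chance level was computed for noncoding genes, and shuffled peaks marked 2.38% of protein-coding genes. The Hox domains contained the long noncoding RNAs Hotair, Haglr and Hottip.

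Replicate 1 had 3.24 times as many X peaks as replicate 2. A general difference in depth or stringency would raise the autosomes as well, and the highest autosomal ratio was 1.08. Weak calls would drop out at a stricter threshold, and with −log10 q of at least 2 the X ratio was 3.33. A larger share of female cells in the pool of replicate 1, whose inactive X carries this mark, may account for the excess. The fold at the 786 shared X peaks was higher in replicate 1 by 0.10 on the log2 scale relative to autosomes. Its 95% bootstrap interval, 0.04 to 0.12, was drawn over peaks, which are not independent. This value decides nothing, as it leaves out the 5486 X peaks of replicate 1 that overlapped no replicate 2 peak. A run difference acting on all chromosomes would have moved the autosomes too, and their ratios of 0.930 to 1.08 argue against it. Of those 5486 X peaks, 7.69% lay at promoters and 46.6% in intergenic sequence, beside 18.6% and 40.5% of all replicate 1 peaks. Chance shares on X alone were not computed. More X copies, more inactive X and a run effect limited to X cannot be told apart. The labels do not give the sex ratio of the pools, and each of these coincides with the replicate.

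Promoters of intermediate CpG content were marked most often. If misplaced 5′ ends caused this, it would vanish in genes whose transcript starts all lie within 500 bp of the 5′ end. Among those genes deciles 5 and 6 were still marked 1.91 times as often as the highest decile. Their shares were 27.4% and 27.7%, against 14.4% in the highest decile, beside 26.6%, 25.9% and 10.3% of all genes. The contrast was thus smaller than among all genes, so a partial role of misplaced 5′ ends is not excluded. Whether peaks were missed at the most CpG-dense promoters stays open. A candidate explanation is that the highest decile holds more genes active in every tissue, which was not tested, as no expression values were used here.

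Of the 8 lists that did not pass the test, those of gastric, smooth muscle, intestinal, liver, squamous and blood genes had 25 of 116 members marked. In the lowest 4 deciles of observed/expected CpG 4 of 88 members were marked (4.55%), beside 5.08% of all genes there. In the other deciles 21 of 28 members were marked (75%), beside 18.6% of all genes there. This share (95% interval 56.6 to 87.3%) lies above that of all genes in the same deciles, which argues against CpG content alone as its source in these 28 members. Among them are transcription factors such as Cdx2, Hhex and Pax9, and the Hox genes Hoxb13 and Hoxd13 of the intestinal list. In the contrast between low and high deciles within the lists, CpG content and the kind of gene cannot be separated. In the other 2 lists, of cell cycle inhibitors and Polycomb proteins, 5 of 29 members of these higher deciles were marked (17.2%).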
